A study of Mus musculus with 6 samples.

How the data were processed

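Polyadenylated RNA of 6 samples of embryonic mouse heart cells was sequenced after library preparation with a Tecan Universal Plus mRNA kit, per the labels' protocols, with 3 libraries of cells expressing wild-type H3.3 and 3 of cells expressing the H3K9M mutant. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the mouse build mm10. Their versions and the strand setting of the counting are not given in the sources used here. The authors deposited a table of raw read counts for each gene, whole numbers for 15159 genes in 6 columns, whose column names match the labels of 1 sample each. The smallest row total is 19, so genes with fewer counts have no row. A second table deposited by the authors holds their own DESeq2 comparison of 14691 genes, with a mean normalised count as a signal over all libraries, a log2 fold change with its standard error, and the p-value with its adjusted p-value. It also holds the Wald statistic, a score deposited by the authors that was not used here.

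The total count of a library lay between 55550379 and 67994773. Genes were filtered with filterByExpr (10 counts minimum, 15 in total), which left 14758 genes, and normalised with TMM. The groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size over the square root of F. The common dispersion was 0.0353, a biological coefficient of variation of 18.8%, and the median standard error over tested genes was 0.133. Levels are CPM (counts scaled by TMM-normalised library size), as mean ± SD of 3 libraries. With 3 libraries against 3, an exact permutation test of 1 gene could not give a p under 0.1, which is why the test pools information across genes.

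The 36 gene lists, the tests, the main alternatives and the rule for named genes were fixed before the data were examined. Lists with 5 or more tested members (34 of 36; those of mitochondrially encoded transcripts and of erythroid and platelet genes had 0 and 3) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry stand beside it. The named genes are the H3.3 genes, the 6 largest rises and 6 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between groups (unnamed gene models and pseudogenes left out), up to 4 members of each list described (the 2 with the smallest p and the 2 with the highest CPM), and Xist with the Y-linked genes. Genes named outside this rule are marked as chosen after their values were seen. Not every gene that the rule allows is reported here. Gene names of 14185 of the 14758 tested genes were found in GENCODE M21, whose build GRCm38 is the one also called mm10.

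Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, TMM factors without the sarcomere, calcium handling and mitochondrial lists, looser and stricter filters, other thresholds, the replicate number as a block, and leaving out each library. Settings added after seeing the data used only replicates 2 and 3 of both groups, counted identical rows once, left out Rn45s, or took the Y-linked level as a covariate. In the counts, 74 genes fall into 33 sets with identical rows, such as Sprr2a1 and Sprr2a2 or Snrpn and Snurf, so such genes hold the same reads and are uncertain. Between pairs of replicates of a group the chi-square per gene was 27.2 to 121.5, so no library is a copy of another. The steps were checked on simulated counts of 14758 genes for the comparison of H3K9M with H3WT, where edgeR recovered 81.0% of 100 genes changed 2-fold and 93.0% of 100 changed 4-fold, with 13 false calls among 187. DESeq2 recovered 86.0% and 94.0% with 52 false calls among 232, and limma-voom 80.0% and 92.0% with 11 among 183. A list shifted by 0.5 on the log2 scale was called in that simulation by camera at either correlation and by fry. Camera at the preset correlation also called 1 of the 33 unshifted lists. The simulated genes were drawn independently, whereas the shifted list, that of the cell cycle, had an estimated correlation of 0.804 in the data. The check therefore does not show what these tests recover from lists of correlated genes.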

Results

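Cells of the mouse heart, taken at embryonic day 18.5 from C57BL/6 x 129S4/SvJae embryos, were profiled by sequencing of polyadenylated RNA after 4 days on a soft silicone (PDMS) substrate of 13 kPa. The cells carried a doxycycline-inducible transgene for histone H3.3, either the wild-type protein (H3WT) or a mutant with methionine in place of lysine 9 (H3K9M), and both groups received doxycycline at 2 µg/ml. Lysine 9 of histone H3 is a methylation site of silenced chromatin, and the mutant histone is known as an inhibitor of its methylation. Each group had 3 libraries. The libraries held between 55550379 and 67994773 counts over 15159 genes. Of these, 14758 genes had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries.

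The comparison of H3K9M with H3WT asks which transcripts differ between heart cells with the mutant and the wild-type histone on a soft substrate. Methylation at lysine 9 is not measured in these data. The 2 genes that encode H3.3 itself did not pass the test. H3f3a was at 1465 ± 125 CPM (SD, n = 3) in H3WT and 1360 ± 109 CPM in H3K9M, with an edgeR adjusted p of 0.653. H3f3b was at 241 ± 18.1 and 216 ± 12.6 CPM, with an edgeR adjusted p of 0.394. Both groups carried an H3.3 transgene, and gene counts do not separate its transcript from the endogenous ones, so these values do not check the labels.

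The 6 largest rises in H3K9M under the naming rule included genes of the cornified envelope of skin and a keratin gene. Sprr2a3, Sprr2a1, Sprr2a2 and Sprr2k encode small proline-rich proteins of that envelope. Sprr2a3 rose from 0.471 ± 0.384 to 40.9 ± 33.1 CPM, a log2 fold change of 6.45 ± 0.77 (SE) with an edgeR adjusted p of 0.00695. Sprr2a1 rose from 1.05 ± 0.580 to 68.0 ± 54.1 CPM, a log2 fold change of 6.03 ± 0.69 (edgeR adjusted p = 0.00606). Sprr2a2 had the same counts as Sprr2a1 in all 6 libraries. Of the 50-base words of Sprr2a1 transcripts 96.3% also occur in another gene, most of them in Sprr2a2, so the 2 genes are 1 measurement. Sprr2k rose by 3.70 ± 0.67 on the log2 scale (edgeR adjusted p = 0.0373) and Krt8, a keratin of simple epithelia, by 3.27 ± 0.46 (edgeR adjusted p = 0.0159). Abca4, a retinoid transporter of photoreceptors, rose from 4.92 ± 1.54 to 23.9 ± 4.17 CPM, a log2 fold change of 2.28 ± 0.24 (edgeR adjusted p = 0.00503). Without H3K9M replicate 1 the log2 fold change was 5.58 for Sprr2a3 and 5.18 for Sprr2a1, and both kept their edgeR call. With limma-voom the adjusted p was 0.209 for Sprr2a3, 0.155 for Sprr2a1 and Sprr2a2, 0.109 for Sprr2k and 0.0916 for Krt8, so these calls were lost, while Abca4 kept its call. The call on Sprr2k was lost without any 1 of 5 libraries, all except H3WT replicate 1, with edgeR adjusted p-values up to 0.109. That on Krt8 was lost without H3WT replicate 2 (0.0979) or H3K9M replicate 2 (0.0649).

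The 6 largest falls under the same rule were in Cd200, Slc1a1, Serpina3n, Rab6b, Ehd3 and Sfrp2. Cd200, an immunoregulatory membrane glycoprotein, fell from 53.2 ± 7.46 to 5.93 ± 0.531 CPM, a log2 fold change of -3.17 ± 0.14 with an edgeR adjusted p of 6.83e-05. Slc1a1, a glutamate transporter, went from 8.31 ± 2.56 CPM to between 0.741 and 0.838 CPM (log2 fold change -3.41 ± 0.28). Serpina3n, a secreted serine protease inhibitor, went from 32.4 ± 22.2 to 3.19 ± 1.43 CPM (-3.34 ± 0.60). The small GTPase gene Rab6b changed by -2.97 ± 0.38 and Ehd3, a gene of endosomal recycling, by -2.59 ± 0.31. Sfrp2, a secreted modulator of Wnt signalling, went from 119 ± 45.5 to 23.4 ± 1.40 CPM (-2.34 ± 0.23). Their edgeR adjusted p-values lay between 6.83e-05 for Cd200 and 0.0362 for Serpina3n. The value for Serpina3n was 0.0981 without H3K9M replicate 1, 0.119 without H3K9M replicate 2, 0.107 without H3K9M replicate 3 and 0.122 without H3WT replicate 2, and 0.184 with limma-voom.

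**Figure D1:**
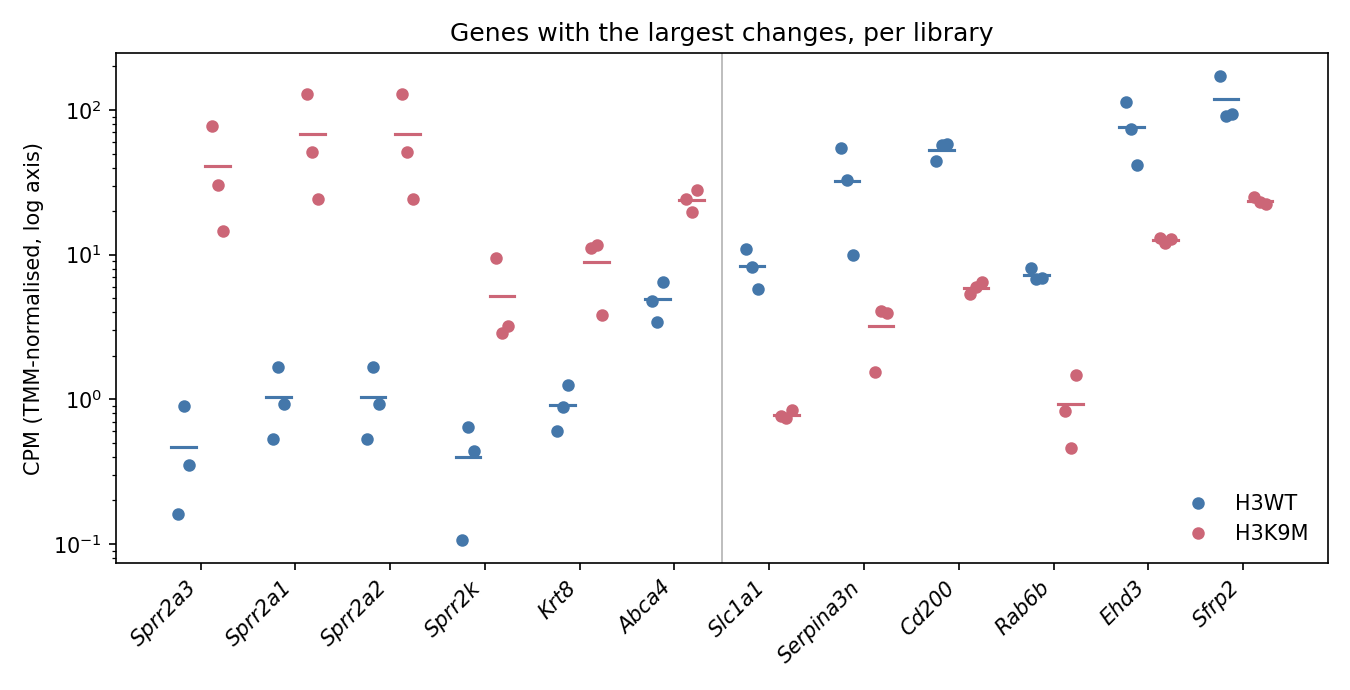
Normalised expression (CPM, log axis) of the 6 genes with the largest rises and the 6 with the largest falls in H3K9M, with a point for each of the 3 libraries of a group and a bar at the group mean. The groups do not overlap for any of the 12 genes because the naming rule required it. The H3K9M libraries differ most among themselves in the Sprr2 genes, as in the SD of 54.1 CPM around a mean of 68.0 CPM for Sprr2a1.

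On mouse build GRCm38 (GENCODE M21) the Sprr2 genes lie together on chromosome 3, with Sprr2a1 at 92215799 to 92221911, Sprr2a3 at 92285417 to 92291405 and Sprr2k at 92432582 to 92433925. Krt8 is on chromosome 15 at 101996698 to 102004482 and Abca4 on chromosome 3 at 122044443 to 122180123. Among the genes that fell, Cd200 is on chromosome 16 at 45382135 to 45409053, Slc1a1 on chromosome 19 at 28835049 to 28913960 and Sfrp2 on chromosome 3 at 83766321 to 83774316. These positions are the spans of whole genes.

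In all, 138 genes were higher and 155 lower in H3K9M at an adjusted p under 0.05 in edgeR's quasi-likelihood test, of which 66 and 76 changed over 2-fold. The groups did not overlap in 22.6% of the tested genes, where chance gives 10%. DESeq2 called 471 and 539 genes, and among them were all 138 and all 155 of the edgeR calls. The counts fell to 49 and 49 without H3K9M replicate 1, to 46 and 50 without H3K9M replicate 2, and to 50 and 54 without H3K9M replicate 3. They were 30 and 30 without H3WT replicate 2, 104 and 89 without H3WT replicate 1 and 149 and 223 without H3WT replicate 3. In the authors' deposited table of the same comparison, 259 genes were higher and 332 lower at an adjusted p under 0.05. Of the 293 genes called here, 288 were in that table, all with the same sign, and 246 passed its threshold. Sprr2a3, the largest rise named here, is not among the 288. Of the named calls that are, Nos3 (authors' DESeq2 adjusted p = 0.186) and Snrpn (0.153) did not pass there.

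Contractile genes stayed high in both groups. Myh6, the main myosin heavy chain of the rodent heart, was at 14926 ± 2157 CPM in H3WT and 15723 ± 1426 CPM in H3K9M. Tnnt2, cardiac troponin T, was at 5890 ± 258 and 6087 ± 87.5 CPM. Of 35 tested genes of the sarcomere list, 1 rose and 0 fell, and 3 rose when adjusted over the list alone. The riser was Myl7, the atrial myosin light chain, from 32.4 ± 7.43 to 86.1 ± 22.4 CPM (log2 fold change 1.41 ± 0.22, edgeR adjusted p = 0.0221). This call was lost without H3WT replicate 2 (0.109), H3K9M replicate 1 (0.0650) or H3K9M replicate 2 (0.0939). The list as a whole was called higher by camera with its preset correlation (median log2 fold change 0.0859, adjusted p = 0.0470), but not with an estimated one (adjusted p = 0.944 with an estimated correlation) and not with a filter of at least 5 CPM in at least 3 libraries (0.0649). Of 19 genes of the fetal and stress programme of cardiomyocytes, none passed over all genes and 1 rose when adjusted over the list alone, while 15 had positive fold changes. Nppb, brain natriuretic peptide, was at 19.4 ± 5.31 CPM in H3WT and 63.1 ± 34.2 CPM in H3K9M (log2 fold change 1.70 ± 0.35, edgeR adjusted p = 0.0518), and Nppa, atrial natriuretic peptide, at 370.5 ± 99.7 and 1068 ± 706 CPM (1.53 ± 0.45, 0.139). Camera called this list higher (median 0.364, adjusted p = 0.00715; adjusted p = 0.944 with an estimated correlation).

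Regulators of heart identity more often had negative than positive fold changes. Of 30 cardiac transcription factors, 22 were negative and 1 passed the test: Irx5, a homeobox gene, from 35.7 ± 3.80 to 17.7 ± 4.28 CPM (log2 fold change -1.01 ± 0.18, edgeR adjusted p = 0.0337). Likewise only this 1 gene fell when adjusted over the list alone. Irx3 (-0.48 ± 0.13), Tbx20 (-0.19 ± 0.10) and Gata4 (-0.12 ± 0.08) did not pass. The list was called lower by camera (median -0.128, adjusted p = 0.0135; adjusted p = 0.944 with an estimated correlation). In the list of calcium handling and membrane excitability, 1 of 32 genes changed, the pacemaker channel gene Hcn4, from 30.8 ± 2.46 to 15.5 ± 4.47 CPM (-0.99 ± 0.19, edgeR adjusted p = 0.0406). In that list 1 rose and 2 fell when adjusted over the list alone. The sarcoplasmic calcium pump gene Atp2a2 was at 3698 ± 325 and 3616 ± 381 CPM. The call on Irx5 was lost without H3WT replicate 1 (0.0657), H3WT replicate 2 (0.116), H3K9M replicate 2 (0.0986) or H3K9M replicate 3 (0.0534). That on Hcn4 was lost without every library but H3K9M replicate 3 (0.0573 to 0.121).

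Among markers of cells other than cardiomyocytes, most endothelial ones had negative fold changes. Of 27 endothelial genes 21 had negative fold changes, 3 fell and 0 rose, and 6 fell when adjusted over the list alone. Npr3, a natriuretic peptide clearance receptor, went from between 10.9 and 13.9 CPM to between 5.22 and 6.72 CPM (log2 fold change -1.09 ± 0.16, edgeR adjusted p = 0.0181). Nos3, endothelial nitric oxide synthase, went from 9.62 ± 1.42 to 4.75 ± 0.995 CPM (-1.02 ± 0.20, edgeR adjusted p = 0.0444). Eng, endoglin, was at 328 ± 23.6 and 332 ± 15.1 CPM. Camera called the list lower (median -0.557, adjusted p = 4.79e-06; adjusted p = 0.641 with an estimated correlation). Of 33 fibroblast and matrix genes 2 rose and 1 fell, and 4 rose and 3 fell when adjusted over the list alone. The proteoglycan gene Vcan went from 334 ± 23.0 to 173 ± 17.9 CPM (-0.95 ± 0.10, edgeR adjusted p = 0.00503). The collagen receptor gene Ddr2 went from 267 ± 28.2 to 422 ± 32.6 CPM (0.66 ± 0.10, 0.0210), and Col1a1 was at 5498 ± 504 and 5930 ± 1015 CPM. In the smooth muscle list Actg2, a smooth muscle actin, rose (1.12 ± 0.20, edgeR adjusted p = 0.0373) and Smtn fell (-0.39 ± 0.08, 0.0443), with 2 rises and 1 fall when adjusted over the list alone. The epicardial and mesothelial list moved apart: Krt7 (1.30 ± 0.16, edgeR adjusted p = 0.00827) and Krt8 rose, Sema3d fell (-0.97 ± 0.16, 0.0254), and 4 rose and 3 fell when adjusted over the list alone. The macrophage gene Lyz2 ranged from 59.2 CPM in H3WT replicate 3 to 269 CPM in H3WT replicate 1 and from 108 to 149 CPM in H3K9M. The call on Nos3 was lost without each of the 6 libraries in turn (0.0753 to 0.126) and with limma-voom (0.0517). That on Npr3 was lost without H3WT replicate 2, H3K9M replicate 1 or H3K9M replicate 2 (0.0607 to 0.0972). Those on Ddr2, Actg2, Smtn and Sema3d were each lost without 2 to 5 libraries, H3WT replicate 2 and H3K9M replicate 2 among them (up to 0.184 for Smtn).

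Targets and feedback regulators of TGF-beta, BMP and Wnt signalling more often had negative than positive fold changes (19 and 8). Of 27 genes 3 fell and 0 rose, and 9 fell and 2 rose when adjusted over the list alone. Besides Sfrp2, the matrix protein gene Tgfbi went from 64.0 ± 4.98 to 34.4 ± 8.75 CPM (log2 fold change -0.90 ± 0.16, edgeR adjusted p = 0.0373). Camera called the list lower (median -0.298, adjusted p = 0.000303; adjusted p = 0.313 with an estimated correlation). In the inflammatory and NF-kB list 20 of 23 genes had negative fold changes and 1 fell, over all genes and adjusted over the list alone: the chemokine gene Cxcl12, from 274.6 ± 48.2 to 110.4 ± 33.8 CPM (-1.31 ± 0.23, edgeR adjusted p = 0.0313). Camera called it lower (median -0.713, adjusted p = 0.00122; adjusted p = 0.769 with an estimated correlation), but not without H3WT replicate 2 (0.0930). The calls on Tgfbi and Cxcl12 were each lost without any 1 of 4 libraries, H3WT replicates 1 and 2 and H3K9M replicate 1 among them for both genes (up to 0.145 and 0.109). Of 23 macrophage and leukocyte markers 20 also had negative fold changes, but none passed over all genes and camera did not call the list (median -0.377, adjusted p = 0.0814). Their camera adjusted p was 1.67e-06 without H3WT replicate 3, 0.0489 without H3K9M replicate 2 and 0.870, with the opposite direction, without H3WT replicate 1. Of 28 immediate early and dissociation genes 26 had positive fold changes and none passed, adjusted over the list alone or over all genes. Camera called this list higher (median 0.326, adjusted p = 0.00715; adjusted p = 0.944 with an estimated correlation), but not without H3K9M replicate 1 (0.606). In that library Egr1, an early growth response gene, stood at 653 CPM against 77.1 to 166 CPM in the H3WT libraries and 87.9 and 89.5 CPM in the other H3K9M libraries.

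In the chromatin pathway itself 1 gene passed the test. Of 36 genes for H3K9 methyltransferases, demethylases and readers 1 changed, over all genes and adjusted over the list alone: Atf7ip, a partner of the methyltransferase SETDB1, rose from 75.6 ± 2.88 to 143 ± 10.6 CPM (log2 fold change 0.92 ± 0.08, edgeR adjusted p = 0.00222). Kdm1a (0.27 ± 0.07) and Trim28 (-0.16 ± 0.08) did not pass. Of the 40 genes on the germline list only 12 were tested. The X-linked homeobox gene Rhox5, already expressed in H3WT, rose from 11.9 ± 1.73 to 28.3 ± 3.36 CPM (1.25 ± 0.14, edgeR adjusted p = 0.00606). It was the 1 of these 12 that passed, over all genes and adjusted over the list alone. The zinc finger gene Zfp37 rose (1.38 ± 0.15, edgeR adjusted p = 0.00534) as the 1 of 69 KRAB genes. Across all tested genes 293 of 14758 passed, so 1 call among the 36 or 69 genes of a list does not set it apart. The same holds for the other lists of 30 or more genes with 1 call. Of 30 imprinted genes 2 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone, with Snrpn at 0.59 ± 0.09 and Peg3 at -0.64 ± 0.07 (edgeR adjusted p = 0.0210 and 0.00606). The call on Snrpn was lost without H3WT replicate 2 (0.109), H3K9M replicate 1 (0.0647) or H3K9M replicate 3 (0.0773). No gene of the clustered protocadherins passed over all genes and 6 of 32 fell when adjusted over the list alone, with Pcdhb17 at -0.88 ± 0.19 and Pcdhb14 at -1.69 ± 0.38. Camera called this list lower (median -0.337, adjusted p = 4.79e-06; adjusted p = 0.641 with an estimated correlation), and several of its genes share exons and therefore counts. None of the 40 cell cycle genes passed, adjusted over the list alone or over all genes, and camera called the list lower (median -0.185, adjusted p = 0.0123; adjusted p = 0.944 with an estimated correlation).

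**Figure D2:**
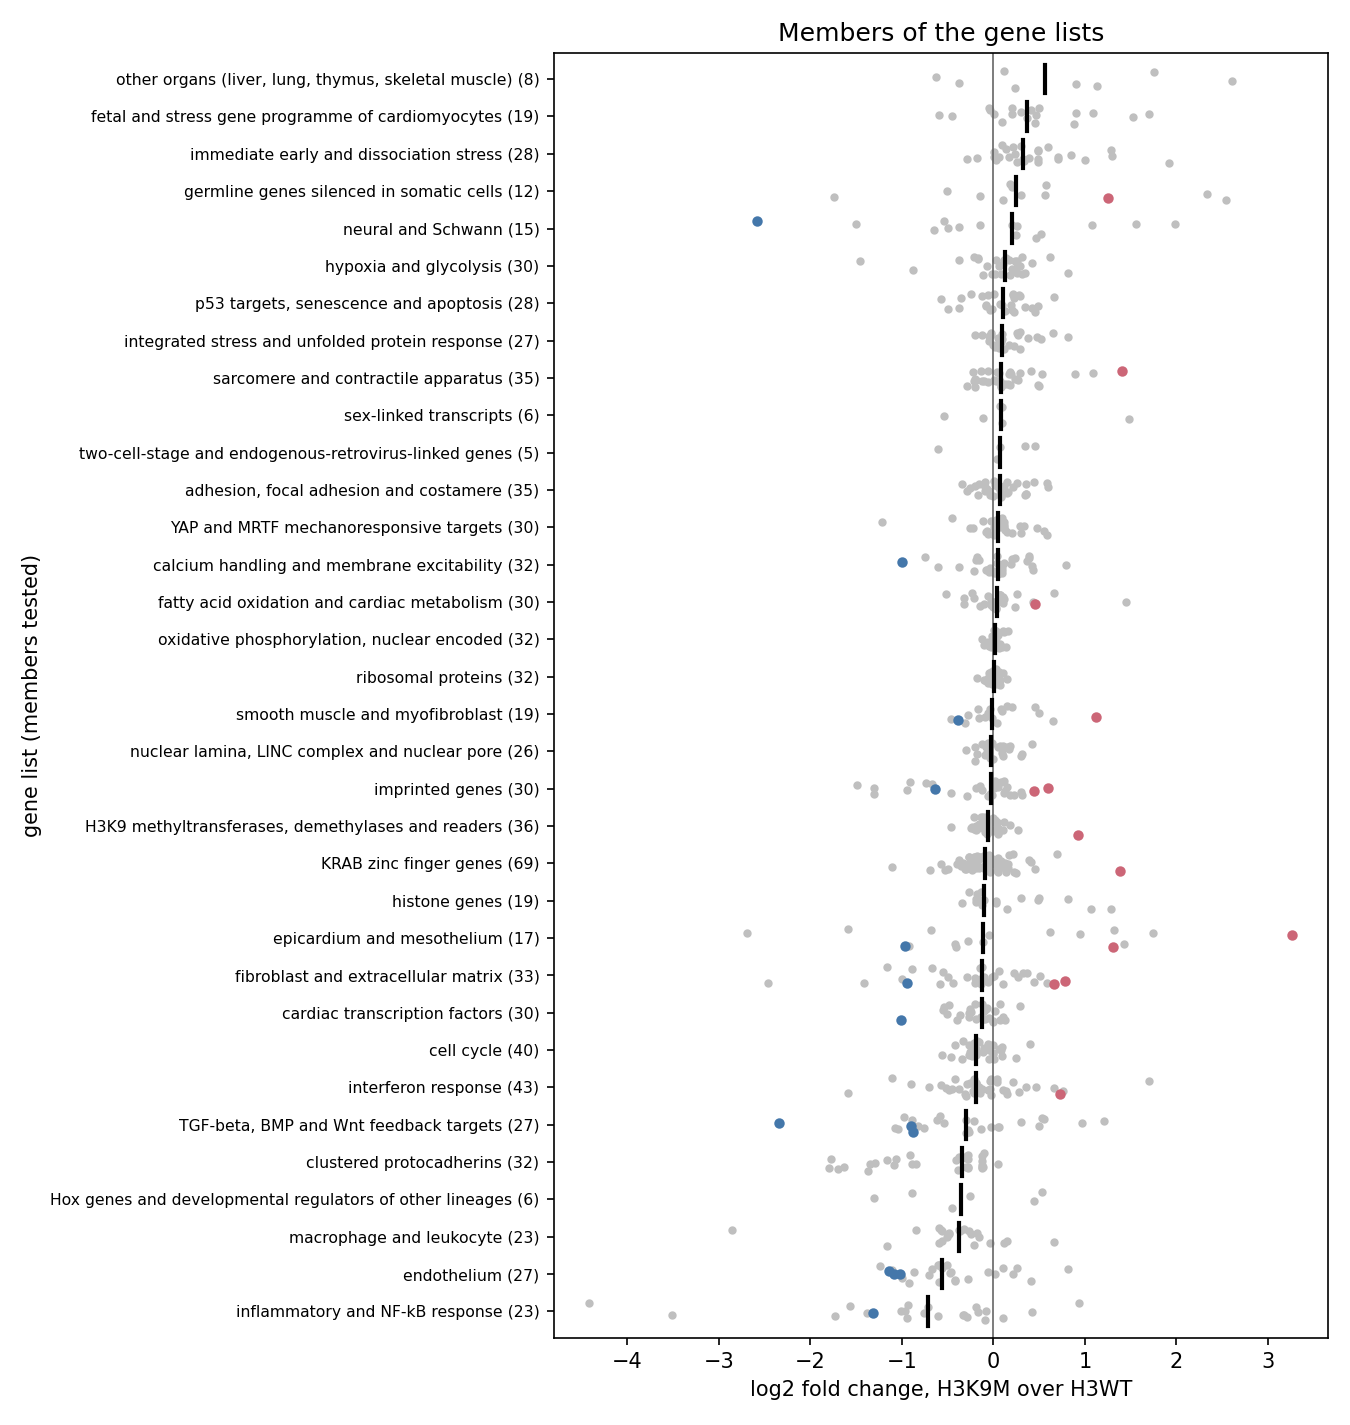
Log2 fold change (H3K9M over H3WT) of the members of the 34 gene lists with 5 or more tested genes, with a point for each gene and a black bar at the list median. Coloured points passed an edgeR adjusted p of 0.05 over all genes (red higher, blue lower in H3K9M), and the medians run from -0.713 in the inflammatory list to 0.569 in the list of other organs.

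Of the 34 lists, camera called 3 higher and 6 lower, and none of the 9 calls held with an estimated correlation or with the directional test of fry. The mixed test of fry, for changes in either direction, passed for 20 of the 34 lists. Its smallest adjusted p, 5e-04, was shared by the neural list, the imprinted list and that of the H3K9 enzymes and readers, where 1 of 36 genes passed in edgeR. Without 1 library at a time, the endothelial, protocadherin and TGF-beta, BMP and Wnt lists kept their camera call in all 6 fits. The inflammatory and immediate early lists lost it in 1 fit each. The sarcomere list lost it without H3WT replicate 1 (0.154), H3WT replicate 2 (0.544) or H3K9M replicate 1 (0.428), and the fetal list without H3WT replicate 1 (0.0896) or H3K9M replicate 1 (0.0924). The cardiac factor list lost it without H3WT replicate 3 (0.120) or H3K9M replicate 2 (0.0916), and the cell cycle list without H3WT replicate 2 (0.0924), H3WT replicate 3 (0.432), H3K9M replicate 2 (0.249) or H3K9M replicate 3 (0.163). In the 9 other splits of the 6 libraries into 3 and 3, camera called 5 to 22 lists, against 9 in the real one.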

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

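The tests of explanations in this part were chosen after the results were seen, except that for the test of read depth the expected outcome was written down before it ran. The authors' deposited table holds 2 genes past an adjusted p of 0.05 that have no row in the count table, which is a signal in data that the comparison here did not use. These are Gm20319, with a log2 fold change of -1.02 and an adjusted p of 0.0114 in the authors' deposited table, and Fam151a, with -1.46 and 0.0138.

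The authors' deposited table was not made from the counts as deposited: its mean normalised count is at the median 0.253 times the mean count of the same gene, and Lyz1, chosen after its values were seen, has a log2 fold change of 2.98 there against -2.85 in the counts (edgeR adjusted p = 0.234). Counting without regard to strand is a candidate explanation for single genes, since genes lying at least 50% under exons of an opposite-strand gene at least 10 times as abundant had a median log2 excess of 1.32 in the authors' deposited table (20 genes), against -0.00485 for 9203 genes with no such exon (permutation p = 1e-04, the smallest that 10000 draws can give). Fewer reads may account for the smaller number of calls, since DESeq2 called 1010 genes in the full counts, 637 in counts thinned to the ratio of the tables and 591 in the authors' deposited table. Both explanations stay open together, and no biological explanation was tested.

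The rise of the Sprr2 genes, of Krt7, Krt8 and of Sprr1a (2.19 ± 0.39, edgeR adjusted p = 0.0362, chosen after its values were seen) was weighed against 3 technical sources. Shared reads are argued against only for the 3 members with under 5% of their 50-base words in another gene, Sprr2k, Sprr1a and Krt7. Their median of 2.19 adds nothing to this, since they were picked as genes that rose. In the edgeR fit without H3K9M replicate 1 the lowest of the log2 fold changes was 1.25, in Krt7. The calls on Sprr2k (adjusted p = 0.0981) and Sprr1a (0.0542) were lost there. That on Sprr1a was also lost without H3WT replicate 1 (0.0670), H3WT replicate 2 (0.150) or H3K9M replicate 2 (0.0965), and with limma-voom (0.0507). The groups did not overlap in any of the 293 called genes, so a rise without replicate 1 was given in advance. The fit therefore shows only that the other H3K9M libraries also stood above those of H3WT. More epicardial or mesothelial cells cannot be told apart from an effect of the mutant histone. The 15 other tested members of that list had a median log2 fold change of -0.275 with an SD of 1.20. Of the 15, 5 were positive: Krt18, Krt19, Msln, Upk3b and Upk1b. The other 10 were negative, from -2.69 in Igfbp5 to -0.0443 in Tbx18, with Wt1 and Sema3d among them. Only Sema3d of the 15 passed the edgeR threshold over all genes. Krt18, Krt19, Msln, Upk3b, Upk1b, Igfbp5 and Wt1 were chosen after their values were seen. Other epithelial cells were not tested, and the assignment of reads between Sprr2a1, Sprr2a2 and Sprr2a3 stays uncertain.

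Most endothelial markers had negative fold changes, with a median of -0.557 on the log2 scale and 3 of 27 past the edgeR threshold, and the camera call on the list was lost (adjusted p = 0.641 with an estimated correlation). A single library as the whole source is argued against, since the weakest of the 6 medians without 1 library was -0.332, without H3WT replicate 3. That median was weaker than -0.557, so the size of the shift depended in part on this library. A lower share of endothelial cells and lower transcript levels within them cannot be told apart here: of the 27 members (SD 0.523) 21 were negative and 6 positive, and their folds differed beyond their standard errors. Of the 6 positive members 4, Eng among them, were more abundant than the median member, and transcripts of such genes in other cells could hide a fall.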

How the results depend on the processing

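In this part, the settings with only replicates 2 and 3 of both groups, identical rows counted once, Rn45s left out or the Y-linked level as a covariate were chosen after seeing the data. The counts of genes higher and lower in H3K9M (138 and 155) stayed within 1.5 times under limma-voom, RLE factors, TMM without the muscle lists, both filters and all 4 added settings. They were 471 and 539 with DESeq2 and 308 and 356 at an adjusted p under 0.1, a looser threshold, and 18 and 15 in glmTreat against a fold of 1.5, a stricter one. On simulated counts DESeq2 made 52 false calls among 232, against 13 among 187 with edgeR. Those counts were drawn for independent genes with the dispersions that edgeR estimated, so they cannot show why DESeq2 called more genes in the data. The cause of its higher counts was not tested. With the replicate number as a block they were 31 and 27. The numbers were not taken as pairs, since the labels do not say that they mark a shared source, and the correlations of same-numbered libraries were -0.157, 0.0346 and -0.0694, and not every library correlated best with its own number. The titles of both replicates 1 share a further mark, as do those of both replicates 3, whose meaning the labels do not give. Those of both replicates 2 differ in that mark, so the replicate block also joined libraries that the marks do not. Rn45s was highest in both replicates 1, so a shared source stays possible. The block's values of 31 and 27 are not those of a block by the marks, which was not fitted. Without 1 library at a time, 30 to 149 genes were higher and 30 to 223 lower, with fewer samples in each fit. Of the 34 named genes that passed, 15 kept their call in all 6 such fits (Sprr2a1, Sprr2a2, Sprr2a3, Abca4, Krt7, Atf7ip, Rhox5, Zfp37, Slc1a1, Cd200, Rab6b, Ehd3, Sfrp2, Vcan and Peg3), and no named gene's call changed direction under any setting. The other 19 lost it without H3WT replicate 2, and Acaa2, Ifi27 and Gap43 are among them. With the replicate number as a block only 18 of the 34 named genes kept their call. With limma-voom 9 named genes lost their call: Sprr2a3 (0.209), Sprr2a1 and Sprr2a2 (0.155), Sprr2k (0.109), Krt8 (0.0916), Sprr1a (0.0507), Serpina3n (0.184), Nos3 (0.0517) and Gap43 (0.0724). With only replicates 2 and 3 of both groups Hcn4, Smtn, Npr3, Nos3, Snrpn, Ifi27, Tgfbi and Acaa2 lost theirs (0.0507 to 0.106), and with the Y-linked level as a covariate Smtn, Nos3 and Ifi27 (0.0523 to 0.0575). The counts of gene lists higher and lower (3 and 6) were 0 and 0 with an estimated correlation and 0 and 0 with fry, at a smallest unadjusted p of 0.00921 and 0.00166, whose cause was not tested. Lists called higher were 7 with the replicate block, 5 with the Y-linked level as a covariate and 0 with only replicates 2 and 3 of both groups, and 1 to 7 without 1 library. The sarcomere list lost its call with the stricter filter (0.0649). Lists called lower were 4 to 7 without 1 library.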

Other observations

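In this part, the tests of neighbouring genes, of silent genes and of other splits of the libraries were chosen after the results were seen. None of the 32 nuclear genes of oxidative phosphorylation or the 32 ribosomal protein genes passed, with list medians of 0.0216 and 0.00966 on the log2 scale. In the list of fatty acid oxidation Acaa2, a mitochondrial thiolase, rose by 0.46 ± 0.08 (edgeR adjusted p = 0.0291), a call lost without every library but H3WT replicate 3. Among interferon genes Ifi27 rose by 0.73 ± 0.13 (edgeR adjusted p = 0.0386), a call lost without H3WT replicate 2 or any of the H3K9M libraries, and in the neural list Gap43, a growth cone protein, fell by 2.59 on the log2 scale (edgeR adjusted p = 0.0313), a call lost without every library but H3WT replicate 1 and with limma-voom (0.0724).

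No gene of the lists for histones, nuclear lamina and pore, YAP and MRTF targets, adhesion, hypoxia and glycolysis, p53 and senescence, unfolded protein response, macrophages, other organs, sex-linked transcripts, Hox genes or genes linked to endogenous retroviruses passed over all genes in edgeR. Adjusted over the list alone, 4 genes of adhesion rose, 3 of hypoxia and glycolysis rose and 1 fell, 1 of the other organs rose, 1 of the retrovirus-linked list rose and 1 of the macrophage list fell, and camera called none of these lists, nor those of calcium handling, fatty acid oxidation, oxidative phosphorylation, ribosomal proteins, fibroblasts, smooth muscle, epicardium, neural cells, H3K9 enzymes, germline genes, KRAB genes, imprinted genes or interferon. The retrovirus-linked list holds ordinary genes and no retroviral transcripts, and only 5 of its 30 members were tested. Of the Hox list, which also holds developmental regulators of other lineages, 6 of 42 were tested. The median differed in sign from the mean and the test for the smooth muscle (-0.0141 and 0.0701), epicardial (-0.116 and 0.148) and nuclear lamina (-0.0213 and 0.0203) lists. For the histone list the median (-0.107) and the test were negative and the mean (0.147) positive.

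The libraries differed in sex-linked transcripts. Xist stood at 71.3, 376 and 353 CPM in H3WT replicates 1, 2 and 3 and at 136, 265 and 149 CPM in those of H3K9M, and did not pass the test (edgeR adjusted p = 0.670). The Y-linked gene Ddx3y stood at 73.4, 33.3 and 29.5 CPM in H3WT and at 41.7, 29.0 and 55.6 CPM in H3K9M (edgeR adjusted p = 0.916). Every library thus held both Xist and Y-linked transcripts, as a mix of male and female cells would. The 45S ribosomal precursor Rn45s, chosen after its values were seen, took 1.02% of the counts in H3WT replicate 1 and 0.904% in H3K9M replicate 1, against 0.374% to 0.582% in the other libraries.

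Genes higher in H3K9M lay close to each other more often than random sets of tested genes. Within 100 kb of another such gene were 19 of the 129 with a known place, against a mean of 3.82 in 10000 random sets (permutation p = 1e-04, the smallest they can give), and of the 149 lower genes 0 were, against a mean of 5.13. A hypothesis is that clusters of neighbouring genes may be released together, as in Sprr2a1, Sprr2a3, Sprr2k and Sprr1a or in Tnfrsf22, Tnfrsf23 and Tnfrsf26 (chosen after their values were seen). Wide blocks of a chromosome, such as strain haplotypes, are another candidate, with 54 higher genes within 2000 kb of another against a mean of 37.86 (permutation p = 0.0106), but 43 against a mean of 33.06 with each local family of similarly named genes counted once (permutation p = 0.0713). With families counted once in the same way, 8 higher genes lay within 100 kb of another against a mean of 3.34 (permutation p = 0.0830). Part of the excess in both windows thus lay within families, and whether the rest exceeds chance stays open. Counting a family once merges the Sprr and Tnfrsf genes whether or not they were released together. It therefore cannot tell joint release from a family counted more than once.

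A further hypothesis was that silent genes may be released in H3K9M. Among called genes under 1 CPM in the lower group 21 rose and 12 fell, against 117 and 143 of the other called genes, an odds ratio of 2.13 with a 95% interval of 0.956 to 4.97 (Fisher's exact test, two-sided, p = 0.0629), which leaves the question open. For the numbers of called genes, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; in edgeR 1 of the 10 splits, the real one, gave as many genes higher (138, highest other 0) and 1 gave as many lower (155, highest other 0). For the lists called by camera with its preset correlation, all 10 splits gave as many in either direction as the 3 higher and 8 gave as many as the 6 lower (highest other 13 in both cases).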
